A study of Homo sapiens with 6 samples.

How the data were processed

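RNA from human cord blood CD34+ cells was sequenced after lentiviral transduction with a hairpin against PRMT4 or a scramble hairpin, 3 samples each. Per the labels' protocols the cells were cultured with 20% BIT9500, SCF at 100 ng/ml, FLT3 ligand at 10 ng/ml, IL6 at 20 ng/ml and TPO at 100 ng/ml, were transduced with 8 µg/ml polybrene, and were sorted for GFP 72 h after transduction. The number of hairpins and of donors is not given in the sources used here.

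The authors deposited 1 table of whole-number read counts per gene symbol, with 16719 genes and 3 rows that name no gene. Per the submitters' processing notes the tools were CASAVA 1.8, TopHat 1.4.0, Bowtie and DESeq 1.10.1 with the build hg19; the counting tool, its strand setting and the annotation are not given in the sources used here. The name of the deposited table calls the counts scaled, but size factors computed on its columns ran from 0.853 to 1.10 and no small whole number was skipped in any library, so the values were treated as unscaled counts. The plan made before the data were examined foresaw limma for scaled values and edgeR if the table held counts, and edgeR was therefore used. Reads that fell on no gene made up 9.76% to 11.2% of a library, ambiguous reads 1.64% to 1.89% and reads aligned to several places 4.69% to 5.99%. These were left out of library sizes and tests. Between samples of the same replicate number, the shares on no gene and aligned to several places were higher in the knockdown in all 3 pairs, and the ambiguous share lower. With the pairing ignored, the group means of these shares did not differ beyond their spread (two-sided exact permutation test, p = 0.6, 0.4 and 0.4). XIST and Y-linked genes (20 symbols) were left out of the tests, and 23 symbols that had been turned into dates are not named. The library totals, the size factors and the share of the 10 most abundant genes were computed with those 20 symbols still in the table. Without strand information, reads of overlapping or antisense genes cannot be told apart. No coordinates are given, because the annotation at hand is of another build than the table.

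Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling and filterByExpr (minimum count 10, minimum total count 15), for knockdown against control with no covariate, two-sided. P-values were adjusted by Benjamini-Hochberg over the 14434 genes kept, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the test's F statistic. Scaled counts are counts divided by the TMM-scaled library size and multiplied by its mean. The common biological coefficient of variation was 17.3%. Genes were named by a rule set before the data were examined. It takes CARM1, the 10 genes with the largest and the 10 with the smallest log2 fold change among called genes whose groups did not overlap and whose mean was at least 100 in the higher group, up to 4 members of each gene list with the smallest p, and RUNX1, DPF2 and the gene of miR-223.

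Of 28 gene lists written before the data were examined, 27 had at least 5 tested members. The list of mitochondrially encoded genes had 0 tested of 26. Lists were tested with camera of limma 3.58.1 on log2(scaled count + 1) with a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move one way without comparing them with other genes. P-values were adjusted over the 27 lists.

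The labels number the replicates 1 to 3 in both groups. Deviations from the group means correlated at 0.479, 0.495 and 0.594 across genes between samples of the same number, so the numbers were taken to pair the samples. This pairing comes from the data, since the labels name no shared donor or day. Pairs within a group differed by far more than counting noise (chi-square per degree of freedom 15.9 to 49.2), so none was counted as a duplicate. The share of counts taken by the 10 most abundant genes was 5.34 ± 0.22% in the control and 6.14 ± 0.34% in the knockdown (SD, n = 3, two-sided exact permutation test, p = 0.1, the smallest possible).

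Words of 7 bases were searched in 3' UTRs of GENCODE transcripts matched by symbol, for 11790 genes (81.7% of those tested) with a 3' UTR of at least 50 bases. For each of 16293 words with at least 30 carriers, a z score compared the ranked fold changes of carriers with those of other genes, with trends on 3' UTR length, its GC content and the mean count removed, and 100 permutations of the fold changes gave the range expected by chance. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

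The steps were tested on simulated data. Counts drawn from the real means, dispersions and library sizes, with 200 changed genes among 14316, gave back 12% of genes changed 1.5-fold, 68% of those changed 2-fold, 88% at 4-fold and 96% at 8-fold, with 14 false calls, and 0 calls when no gene was changed. A list shifted by 0.5 on the log2 scale was called and 0 of the others were. Genes were drawn independently there, so this does not show how often camera calls lists whose members vary together, as in the real data. The real fit called 4923 of 14434 genes, far more than the 200 changed in the simulation. The shares of genes given back need not hold for the real fit. A planted word with a shift of -0.3 was recovered by the word search over 11790 genes. The alternatives tried were DESeq2 1.42.0, other scalings and count filters, limma with several pseudocounts and variance models, the replicate block, and leaving out each sample.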

Results

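Gene expression was measured by RNA sequencing in CD34+ hematopoietic stem and progenitor cells purified from human umbilical cord blood. The cells had been transduced with a lentivirus carrying a short hairpin RNA against PRMT4, a protein arginine methyltransferase encoded by CARM1, or with a scramble control hairpin. Each group held 3 samples, and the 1 comparison of the design asks which genes change when PRMT4 is knocked down. GFP-positive cells were sorted 72 h after transduction. The control libraries held 26038692, 28313083 and 21396469 reads counted on genes for replicates 1, 2 and 3. The knockdown libraries held 22940752, 27478977 and 27122735. The mean totals of the groups did not differ beyond their spread (two-sided exact permutation test, p = 0.7, where 3 samples against 3 cannot give less than 0.1). The labels do not say that the replicates came from separate donors or cultures, so the p-values measure the spread between these samples, which may be technical.

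CARM1 was lower in all 3 knockdown samples than in all 3 control samples. Its scaled read count was 1928 ± 142 (SD, n = 3) in the control and 362 ± 19.1 (SD, n = 3) in the knockdown, so that 18.8% of the control level remained. The lowest control sample stood at 1818 and the highest knockdown sample at 373. The log2 fold change was -2.41 with a standard error of 0.10 (edgeR quasi-likelihood test, adjusted p = 5.24e-05), the smallest p but 1 of all 14434 genes tested. The first principal component, with 58.7% of the variance, separated the groups. The second, with 23.1%, set replicate 3 of both groups apart from the other samples.

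**Figure D1:**
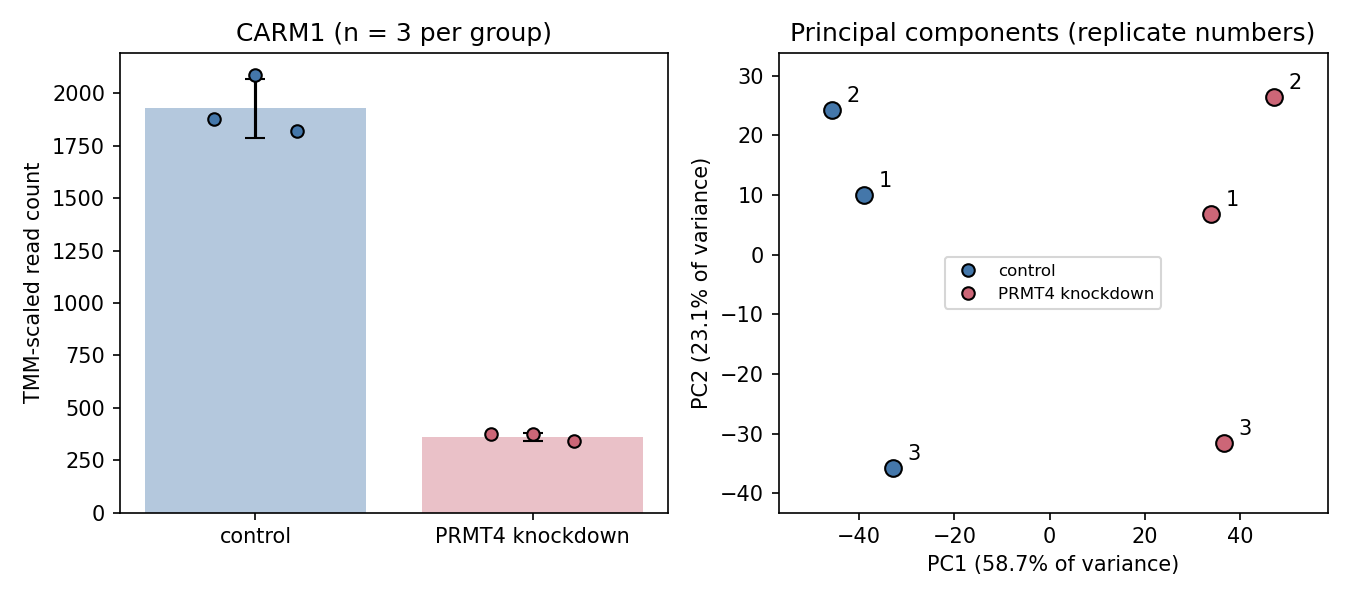
Left, scaled read counts of CARM1 in each sample (points), with the group means (bars) and SD (error bars, n = 3). Right, the first and second principal components of all tested genes, in arbitrary units, with replicate numbers beside the points; the groups part on the first component, which holds 58.7% of the variance.

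Of the 14434 genes tested, 2361 were higher and 2562 were lower in the knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 667 of the higher and 631 of the lower genes. With the replicate number as a block the counts were 3638 higher and 3518 lower, and these included all 2361 and all 2562 genes. Leaving out control replicate 1 gave 1497 higher genes.

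Among called genes whose groups did not overlap and whose mean was at least 100 in the higher group, the complement gene C3 rose most, from 36.0 ± 9.26 scaled counts in the control to 977 ± 222 in the knockdown (SD, n = 3), a log2 fold change of 4.75 (SE 0.25, adjusted p = 0.000116). HMCN1, which encodes an extracellular matrix protein, rose by 4.63 on the log2 scale (SE 0.32), and CYP27A1, the sterol 27-hydroxylase, by 4.09 (SE 0.71). The other large rises were those of HSD11B1 (3.99), EMR1 (3.79), EDNRB (3.63), CRHBP (3.54), VNN2 (3.46), the sphingosine-1-phosphate receptor gene S1PR1 (3.34) and MAFB (3.29), a transcription factor gene of the monocyte lineage. CD1A, which encodes an antigen-presenting molecule of dendritic cells, had the largest fall among the same genes, from 837 ± 485 to 12.3 ± 7.29 scaled counts (SD, n = 3), a log2 fold change of -6.10 (SE 0.65, adjusted p = 0.000738). CD1C of the same family fell by 3.86 (SE 0.51). The platelet glycoprotein gene GP5 fell by 4.04 with a standard error of 0.99, and the platelet receptor gene TREML1 by 3.98 with a standard error of 0.65. The remaining large falls were FAM178B (-3.75), RBPMS2 (-3.47), TNFRSF21 (-3.34), the noncoding RNA UCA1 (-3.15), CALD1 (-3.10) and PDE5A (-3.03). Control counts of GP5 and CALD1 varied widely, at 358 ± 357 and 224 ± 188 (SD, n = 3).

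**Figure D2:**
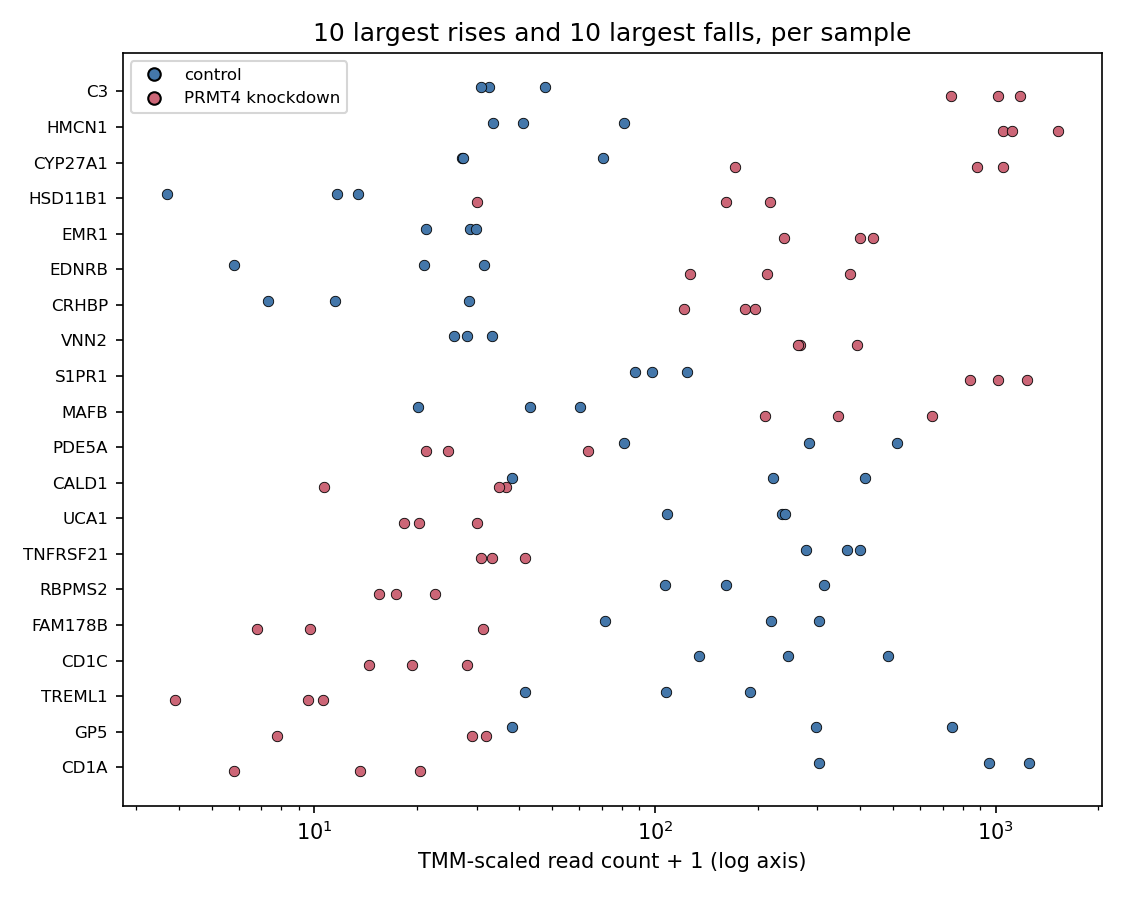
Scaled read counts plus 1 (log axis) of the 10 genes with the largest rise and the 10 with the largest fall among genes that passed the test without overlap of the groups and with a mean of at least 100 in the higher group; each point is 1 sample. C3 went from a mean of 36.0 to 977 and CD1A from 837 to 12.3.

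Cell cycle genes fell together. All 35 tested genes of the G2/M and mitosis list fell, over all genes and adjusted over the list alone, with a median log2 fold change of -1.04 (camera, adjusted p = 6.48e-18, and adjusted p = 0.487 with an estimated correlation). HMMR, a spindle protein gene, fell by 2.47 (SE 0.11), the kinesin gene KIF2C by 2.16 (SE 0.13), and the phosphatase gene CDC25C by 1.51 (SE 0.16). CDCA3 fell by 1.37 (SE 0.13). Of these genes all but CDCA3 carry a 3' UTR match of at least 7 bases to the site described below, which 4 of the 35 list members hold. In the G1/S and replication list 31 of 32 genes fell, and 32 adjusted over the list alone, with a median of -1.12 (camera, adjusted p = 1.60e-17, and adjusted p = 0.487 with an estimated correlation). CCNE2, which encodes cyclin E2, fell by 1.93 (SE 0.16), UHRF1 by 1.89 (SE 0.18) and the replication factor gene CDC45 by 1.57 (SE 0.17). FEN1 fell by 1.29 (SE 0.11). CCNE2 and UHRF1 carry such a match, which 5 of the 32 list members hold. Of 32 genes of ribosome biogenesis and MYC induction 31 fell, also adjusted over the list alone, with a median of -0.88 (camera, adjusted p = 4.08e-15, and adjusted p = 0.487 with an estimated correlation). POLR1A, the largest subunit of RNA polymerase I, fell by 1.38 (SE 0.15) and the processing factor gene BOP1 by 1.20 (SE 0.13). Among 52 cytosolic ribosomal protein genes 1 was higher, RPL15 at 0.45 (SE 0.12), and none adjusted over the list alone, with a median of 0.10. That list was not called (camera, adjusted p = 0.197) but was with the replicate block (adjusted p = 0.0289, and adjusted p = 0.806 with the block and an estimated correlation), and reads of these genes may be shared with their pseudogenes.

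In the lists of monocyte and late neutrophil genes more members rose than fell. Of 32 monocyte and macrophage markers 17 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.08 (camera, adjusted p = 7.75e-05, and adjusted p = 0.528 with an estimated correlation). The inhibitory receptor gene LILRB1 rose by 2.66 (SE 0.18), TLR2 by 2.13 (SE 0.23), LILRB2 by 2.11 (SE 0.24) and the proteoglycan gene VCAN by 1.91 (SE 0.22). Reads of the LILR genes may be shared within their family. In the late neutrophil list 8 of 19 genes rose and 1 fell, against 11 and 1 adjusted over the list alone, with a median of 0.99 (camera, adjusted p = 0.00483, and adjusted p = 0.528 with an estimated correlation). The calcium-binding protein genes S100A8 and S100A9 rose by 2.51 (SE 0.43) and 1.53 (SE 0.39), and CSF3R, the G-CSF receptor gene, by 0.99 (SE 0.14). NCF1 rose by 1.59 (SE 0.24), and its reads may be shared with near-identical pseudogenes. Genes of the primary granule and promyelocyte list moved both ways, with 3 of 15 higher and 2 lower, the same adjusted over the list alone, a median of 0.42 and no call (camera, adjusted p = 0.775). Within them CFD rose by 1.51 (SE 0.27) and CSTA by 1.59 (SE 0.41), while CST7 fell by 2.04 (SE 0.27) and CLEC11A by 1.31 (SE 0.14). Of 19 myeloid transcription factor genes 11 rose and 1 fell, also adjusted over the list alone, with a median of 0.78 (camera, adjusted p = 0.00178, and adjusted p = 0.487 with an estimated correlation). CEBPD rose by 2.46 (SE 0.18), CEBPA by 1.57 (SE 0.14), IRF8 by 1.37 (SE 0.17) and GFI1 by 1.01 (SE 0.12). Tested by itself with fry, neither the monocyte nor the late neutrophil list passed, at adjusted p = 0.0609 and 0.0886.

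Of 39 lysosome and autophagy genes 25 rose and 1 fell, against 28 and 1 adjusted over the list alone, with a median log2 fold change of 0.56 (camera, adjusted p = 4.25e-08, and adjusted p = 0.487 with an estimated correlation). GABARAPL1, an autophagosome protein gene, rose by 1.30 (SE 0.15), the protease gene CTSA 2.01-fold, the kinase gene ULK1 by 0.98 (SE 0.12) and ATG14 by 0.90 (SE 0.09).

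Of 27 megakaryocyte and platelet genes 12 fell and 1 rose, against 14 and 2 adjusted over the list alone, with a median log2 fold change of -0.70 (camera, adjusted p = 0.00453, and adjusted p = 0.659 with an estimated correlation). GP6, the collagen receptor gene of platelets, fell by 2.16 (SE 0.45), SPARC by 0.84 (SE 0.16) and the integrin gene ITGA2B by 0.70 (SE 0.12). The call was lost without control replicate 2 (adjusted p = 0.0509) and with fry (adjusted p = 0.197). Of 26 stem and progenitor markers 9 rose and 2 fell, against 11 and 2 adjusted over the list alone, with a median of 0.53 (camera, adjusted p = 0.00463, and adjusted p = 0.528 with an estimated correlation). CRHBP and the transcription factor gene ERG rose by 3.54 (SE 0.47) and 2.05 (SE 0.13), PROCR by 1.61 (SE 0.24) and SOX4 2.64-fold. Among 33 erythroid genes 3 rose and 6 fell, also adjusted over the list alone, with a median of -0.13 (camera, adjusted p = 0.682). The band 3 anion exchanger gene SLC4A1 rose by 1.95 (SE 0.27) and ALAS2 by 0.70 (SE 0.11), while APOC1 fell by 1.14 (SE 0.17) and HEMGN by 0.60 (SE 0.14). Of 18 dendritic cell genes 2 rose and 3 fell, also adjusted over the list alone, with a median of 0.10, a mean of -0.50 and no call (camera, adjusted p = 0.682). The falling members were CD1A, CD1C and CD1E (-2.60, SE 0.41), and CIITA was among the rising members at 0.62 (SE 0.09).

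None of 19 mast cell, basophil and eosinophil genes passed in edgeR over all genes or adjusted over the list alone, against 3 at an unadjusted p under 0.05 and 3 in DESeq2. Their median was -0.21 and their mean 0.03 (camera, adjusted p = 0.339). FCER1A stood at -0.52 (SE 0.19, adjusted p = 0.0711), SLC18A2 at -0.61 (SE 0.23), IL5RA at 1.94 (SE 0.77) and PRG3 at 2.06 (SE 0.96). With the replicate block all 4 passed (adjusted p = 0.00987, 0.000311, 0.00086 and 0.00123). Without knockdown replicate 2 the list was called lower (adjusted p = 0.0082). Of 12 lymphoid genes 2 rose, CD79B by 0.67 (SE 0.13) and NKG7 by 0.65 (SE 0.16), and LEF1 fell by 1.47 (SE 0.26), with the same counts adjusted over the list alone, a median of -0.10 and no call (camera, adjusted p = 0.989). IGLL1 stood at -0.78 (SE 0.43, adjusted p = 0.202, and 0.035 with the replicate block). Of 12 endothelial and stromal genes 3 rose and none fell, also adjusted over the list alone, with a median of 0.34 and no call (camera, adjusted p = 0.437). These were KDR at 2.06 (SE 0.48), TEK at 1.13 (SE 0.22) and ROBO4 at 1.12 (SE 0.31), while PDGFRB stood at -0.59 (SE 0.23, adjusted p = 0.0798, and 0.0391 with the replicate block).

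**Figure D3:**
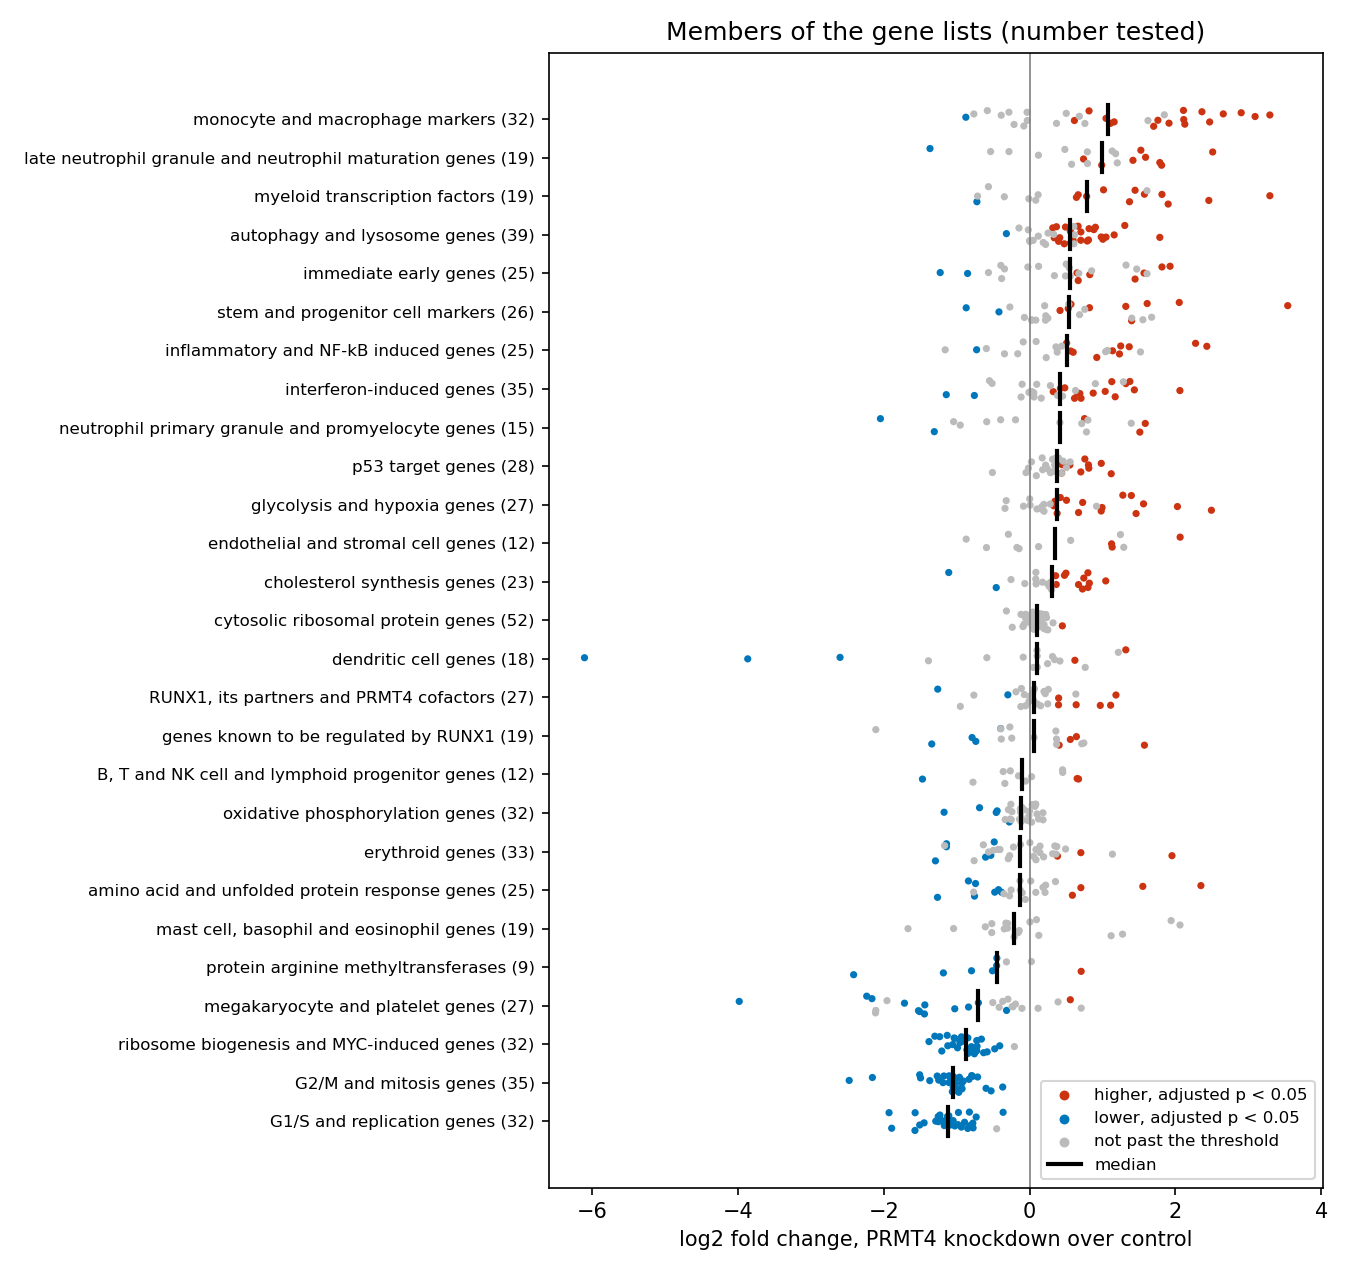
Log2 fold changes (knockdown over control) of the tested members of 27 gene lists; each point is 1 gene, red or blue where its edgeR adjusted p was under 0.05, and black bars are list medians. Medians ran from -1.12 for G1/S genes to 1.08 for monocyte and macrophage markers.

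Several stress and metabolic lists were higher. Of 27 glycolysis and hypoxia genes 15 rose and none fell, against 16 and 2 adjusted over the list alone, with a median log2 fold change of 0.38 (camera, adjusted p = 2.81e-05, and adjusted p = 0.487 with an estimated correlation). BNIP3 rose by 2.03 (SE 0.19), NDRG1 by 1.56 (SE 0.11), the aldolase gene ALDOC by 1.39 (SE 0.14) and the phosphoglycerate kinase gene PGK1 by 0.99 (SE 0.09). In the cholesterol synthesis list 11 of 23 genes rose and 2 fell, against 13 and 3 adjusted over the list alone, with a median of 0.30 (camera, adjusted p = 0.000486, and adjusted p = 0.487 with an estimated correlation). SC5DL rose by 1.04 (SE 0.14), the lanosterol synthase gene LSS by 0.82 (SE 0.11), INSIG1 by 0.80 (SE 0.10) and STARD4 by 0.67 (SE 0.09). Of 28 p53 target genes 9 rose and none fell, against 12 and none adjusted over the list alone, with a median of 0.38 (camera, adjusted p = 0.000398, and adjusted p = 0.614 with an estimated correlation). CCNG1 rose by 0.98 (SE 0.13), RRM2B by 0.81 (SE 0.18), ZMAT3 by 0.76 (SE 0.17) and BBC3 by 0.70 (SE 0.18), and fry did not call this list (adjusted p = 0.147). Of 32 oxidative phosphorylation genes 5 fell and none rose, also adjusted over the list alone, with a median of -0.11 and no call (camera, adjusted p = 0.0529). With the replicate block that list was called (adjusted p = 0.0499, and adjusted p = 0.806 with the block and an estimated correlation). ATP5G1 fell by 1.17 (SE 0.13), ATP5B by 0.69 (SE 0.09), COX5B by 0.46 (SE 0.08) and UQCRQ by 0.44 (SE 0.09).

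Of 35 interferon-induced genes 15 rose and 2 fell, also adjusted over the list alone, with a median log2 fold change of 0.42 (camera, adjusted p = 0.00101, and adjusted p = 0.487 with an estimated correlation). IFIT2 rose by 1.44 (SE 0.19), IRF9 by 1.37 (SE 0.18), IFIT3 by 1.17 (SE 0.13) and SAMD9L by 1.04 (SE 0.12). In the inflammatory and NF-kB list 10 of 25 genes rose and 1 fell, against 11 and 2 adjusted over the list alone, with a median of 0.51 (camera, adjusted p = 0.0125, and adjusted p = 0.528 with an estimated correlation). CCL3 rose by 2.43 (SE 0.33), although its reads may be shared with near-identical copies, ICAM1 rose by 1.37 (SE 0.22) and SOD2 by 1.23 (SE 0.18), and NFKB1 fell by 0.73 (SE 0.14). Of 25 immediate early genes 7 rose and 2 fell, against 10 and 2 adjusted over the list alone, with a median of 0.56 (camera, adjusted p = 0.0213, and adjusted p = 0.614 with an estimated correlation). EGR2 rose by 1.81 (SE 0.26), FOS by 1.57 (SE 0.30), JUNB by 0.67 (SE 0.13) and JUND by 0.65 (SE 0.13). That call was lost without control replicate 2 (adjusted p = 0.0516), without knockdown replicate 3 (0.0648), with a stricter count filter (0.0594) and with fry (0.115). Among 25 genes of the amino acid and unfolded protein responses 4 rose and 7 fell, also adjusted over the list alone, with a median of -0.13 and no call (camera, adjusted p = 0.339). The receptor gene VLDLR rose by 2.35 (SE 0.29), and PDIA4 fell by 1.26 (SE 0.14), SLC7A5 by 0.76 (SE 0.14) and HSP90B1 by 0.48 (SE 0.10).

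The list of protein arginine methyltransferases holds CARM1, the target of the knockdown, and WDR77, a partner of PRMT5 that is not a methyltransferase. Of its 9 genes 6 fell and 1 rose, against 7 and 1 adjusted over the list alone, with a median log2 fold change of -0.45 (camera, adjusted p = 0.00463, and adjusted p = 0.487 with an estimated correlation). Without CARM1 the 8 other genes had a median of -0.45 (camera, adjusted p = 0.0297, and adjusted p = 0.528 with an estimated correlation), and without WDR77 as well the call was lost at a median of -0.45 (adjusted p = 0.103). WDR77 fell by 1.18 (SE 0.14) and PRMT5 by 0.80 (SE 0.13), while PRMT2 rose by 0.71 (SE 0.11). Of 27 genes for RUNX1, its partners and PRMT4 cofactors 6 rose and 2 fell, also adjusted over the list alone, with a median of 0.07 and no call (camera, adjusted p = 0.295). CBFB, whose protein binds RUNX1 and strengthens its binding to DNA, fell by 1.26 (SE 0.13), and the coactivator genes NCOA3, KAT2B and NCOA2 rose by 1.18 (SE 0.14), 0.97 (SE 0.10) and 0.64 (SE 0.11). RUNX1 itself stood at -0.01 (SE 0.10, adjusted p = 0.949). DPF2, a chromatin remodelling factor gene, rose by 0.40 (SE 0.09, adjusted p = 0.0119). Among 19 genes known to be regulated by RUNX1 4 rose and 4 fell, against 4 and 5 adjusted over the list alone, with a median of 0.06 and no call (camera, adjusted p = 0.996). The cytokine receptor gene CSF2RB fell by 1.34 (SE 0.13), UBASH3B by 0.79 (SE 0.12) and CCND3 by 0.74 (SE 0.11), while CEBPA rose. The gene of miR-223 was not analysed here.

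The lists were fixed before the data were examined, and no list that camera called with its preset correlation of 0.01 was called with an estimated correlation. That estimate rests on the residuals of 6 samples, so a lost call does not show that a list stayed unchanged. Fry called G1/S, G2/M, glycolysis, cholesterol, myeloid transcription factor and methyltransferase genes (each adjusted p = 0.00815), and ribosome biogenesis genes (0.00891). It also called interferon (0.00969), lysosome (0.0136), stem and progenitor (0.0327) and inflammatory genes (0.0417), without comparing them with other genes. With the replicate block more members passed in many lists. Ribosomal protein genes then numbered 14 higher and 2 lower, mast cell, basophil and eosinophil genes 3 and 7, erythroid genes 7 and 13, megakaryocyte genes 3 and 20, and primary granule genes 8 and 5. Dendritic cell genes numbered 6 higher and 5 lower, endothelial and stromal genes 6 and 2, lymphoid genes 2 and 2, stem and progenitor markers 14 and 2, late neutrophil genes 13 and 1, monocyte and macrophage markers 20 and 2, and myeloid transcription factor genes 12 and 4. Immediate early genes numbered 16 higher and 4 lower, p53 targets 17 and 1, interferon-induced genes 18 and 4, inflammatory genes 13 and 3, glycolysis and hypoxia genes 19 and 2, and oxidative phosphorylation genes 0 and 11. RUNX1 partners and PRMT4 cofactors numbered 11 and 4, and genes regulated by RUNX1 8 and 6. In no other list did a count move by over 1.5 times.

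Transcripts with the word TCCTTCT in the 3' untranslated region (UTR) were lower than others. Among 11790 tested genes with a searched 3' UTR, the 375 with the 8-base site TCCTTCTA had a median log2 fold change of -0.17, those with TCCTTCT alone -0.07, those with CCTTCTA alone -0.14, and those with none 0.06. Carriers had longer 3' UTRs, with medians of 3446, 2630 and 2399 bases against 603 for genes with none. Genes with none, taken to match the 3' UTR lengths of each class, had medians of 0.09. The word was picked from 16293 words on these fold changes, so a test on the same genes is not independent of that choice. The genes were also divided at random into equal parts. Searched alone, one part gave TCCTTCT as the lowest word and the other gave CCTTCTA. In the 5895 genes of the other part, 41 of the 100 falling genes with the smallest p carried TCCTTCT, against 18.0 expected from 3' UTR length (exact conditional test within classes of length, two-sided, p = 1.78e-09). This test was chosen after the results were seen. It takes genes as independent, but both parts come from the same 6 libraries, in which genes may vary together. Its p-value therefore does not measure the spread between samples. A match of at least 7 bases was present in 31.3% of the lower genes, in 15.1% of the higher genes and in 21.1% of genes that did not pass. Of the falling genes named here, CARM1, CD1A, HMMR, KIF2C, CDC25C, CCNE2, UHRF1, POLR1A, TNFRSF21, PDE5A, PDIA4, COX5B, WDR77, CCND3 and NFKB1 carried such a match, and so did the rising ALDOC, EDNRB, ERG, GABARAPL1, GFI1, LSS, PGK1, SOD2, VCAN and VLDLR. Without the genes found to carry one, 1757 genes were higher and 2080 lower of 11866 tested. Genes whose 3' UTR was not searched stayed in this fit, so it may still hold carriers. The methyltransferase list lost its carriers CARM1 and WDR77. Left with the same 7 members as above and a median of -0.50, it was no longer called (camera, adjusted p = 0.0685).

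**Figure D4:**
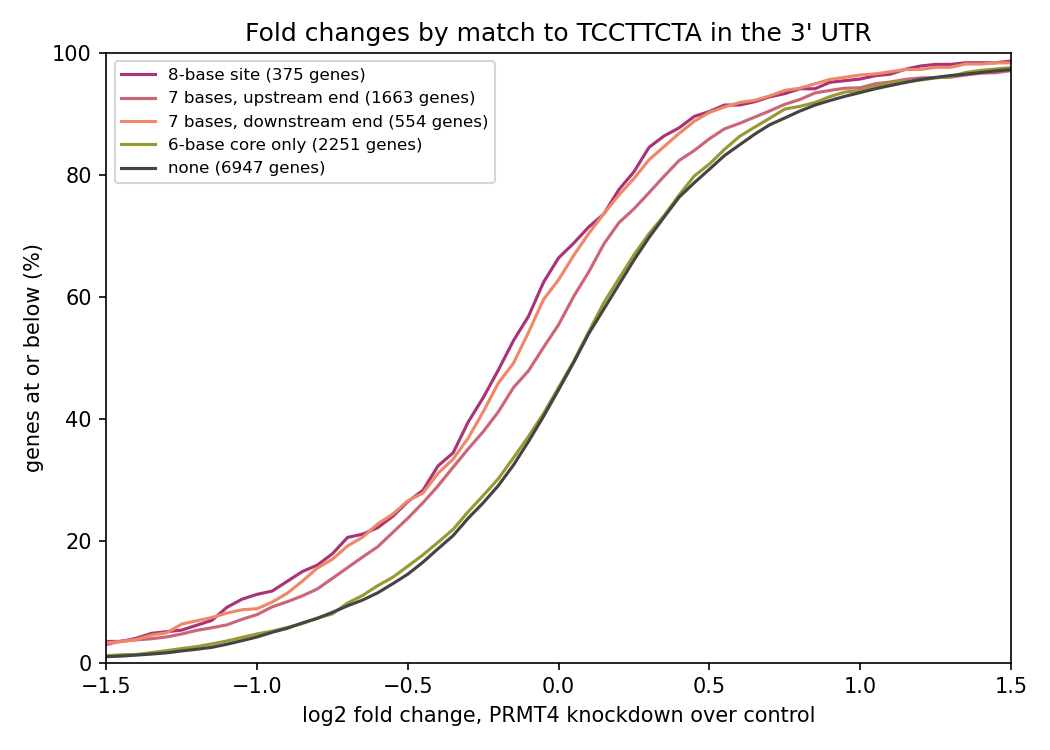
Cumulative share of genes (%) by log2 fold change (knockdown over control), for genes whose 3' UTR holds the 8-base site TCCTTCTA, 7 bases at either of its ends, the 6-base core alone, or none. The curve of the 375 genes with the 8-base site lies to the left of that of genes with none, with medians of -0.17 and 0.06. The classes also differ in 3' UTR length, with medians of 3446 and 603 bases.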

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

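The limma fit with a pseudocount of 1, the fits without genes that carry the 3' UTR word, the replicate block joined to an estimated correlation, and the methyltransferase list without CARM1 or WDR77 were chosen after the results were seen. The log2 fold change of CARM1 lay between -2.48 and -2.35 in every setting run. Higher genes numbered 1757 to 3638 and lower genes 2080 to 3518 over the settings that used all samples, and 1497 to 2092 higher genes and 1842 to 2595 lower genes passed with 1 sample left out. The counts of 1757 and 2080 came from the fit without genes found to carry the word. That fit tested 11866 genes against 14434 in the main fit, and genes with no searched 3' UTR stayed in it. The lowest higher count, 1497, came without control replicate 1. The replicate block moved the higher count to 3638 and called the ribosomal protein list (0.0289) and the oxidative phosphorylation list (0.0499); it changed no other list call of the main test, and 9 named genes that had not passed then did. Other scalings moved the median of all genes by less than 0.1. Fewer samples leave fewer degrees of freedom, and no other cause below was tested.

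Values for lists are adjusted p. With an estimated correlation all 16 called lists lost their call, at 0.487 (myeloid transcription factors, methyltransferases, G1/S, G2/M, interferon, cholesterol, ribosome biogenesis, glycolysis, lysosome), 0.528 (stem, late neutrophil, monocyte, inflammatory), 0.614 (p53, immediate early) or 0.659 (megakaryocyte). With the replicate block as well they stood at 0.570, or at 0.606 for p53 and methyltransferases, and the ribosomal protein and oxidative phosphorylation lists, called with the block alone, at 0.806. Tests with an estimated correlation draw it from the residuals of 6 samples, which leaves few degrees of freedom. Even G2/M was not called, although all 35 of its genes passed. A lost call there therefore does not show that a list stayed unchanged. Fry gave no call for late neutrophil (0.0886), monocyte (0.0609), megakaryocyte (0.197), p53 (0.147) and immediate early genes (0.115), called RUNX1 partners (0.0121), and turned the direction of primary granule (0.971) and RUNX1 target genes (0.844). The other lists called in the main test kept their call with fry. The count filter at a mean of 100 ended the immediate early call (0.0594) and turned primary granule (0.923) and lymphoid genes (0.576). No filter turned lymphoid genes (0.795) and called oxidative phosphorylation (0.0322). Quantile normalization turned dendritic genes (0.977), and sample weights turned them (0.869) and called ribosomal proteins (0.0202). Without genes carrying the 3' UTR word, the unfolded protein response (0.0457) and oxidative phosphorylation lists (0.0137) gained a call. Methyltransferases lost theirs (0.0685), at a median log2 fold change of -0.50 against -0.45. The members removed were CARM1 and WDR77, which left the same 7 genes as dropping these by name. Without CARM1 the methyltransferase call was kept (0.0297), and without WDR77 as well it was lost (0.103) at a median of -0.45.

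Leaving out 1 sample gave ranges of 0.0762 to 0.958 for primary granule, 0.196 to 0.892 for erythroid, 0.387 to 0.976 for dendritic, 0.766 to 0.961 for lymphoid and 0.528 to 0.976 for RUNX1 target genes, each with a turned direction in at least 1 of them. Megakaryocyte genes ranged from 4.50e-05 to 0.0509 (lost without control replicate 2) and immediate early genes from 0.00186 to 0.0648 (lost without control replicate 2, at 0.0516, and knockdown replicate 3). Mast cell genes ranged from 0.0082 (called without knockdown replicate 2) to 0.727, where the direction turned without knockdown replicate 3. Ribosomal proteins ranged from 0.0113 to 0.742, called without control replicate 3 or knockdown replicate 1 or 2 and turned in direction without knockdown replicate 3 (0.516), and oxidative phosphorylation from 0.00969 to 0.342, called without control replicate 1 or 3 or knockdown replicate 2 or 3. RUNX1, which did not pass, stood at a log2 fold change of 0.0034 with the filter at 100, 0.061 with sample weights and between -0.0805 and 0.053 with 1 sample left out. Of 124 named genes, 105 kept their side of the threshold and their direction in every setting.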

Other observations

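The tests of base composition, of 3' UTR length, of direct silencing of list members, of indirect effects, of the mixture of cells and of the word in genes kept out of its search, and the 20 gene families below, were chosen after the results were seen.

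Families of related genes, some of whose members the fixed lists also hold, were counted after the values were seen (20 families). Their members may be regulated together, and no family was called by camera with an estimated correlation (adjusted p = 0.274 or more), so the counts describe these genes and are no tests. Of 9 leukocyte immunoglobulin-like receptor genes 8 rose, with a median log2 fold change of 2.11, among them LILRA2 at 2.33 (SE 0.21) and LILRB4 at 2.36 (SE 0.55), although reads may be shared within this family. Of 10 Toll-like receptor genes, sensors of microbial molecules, 6 rose, with a median of 1.09. TLR8 rose by 2.74 (SE 0.48), TLR4 by 1.70 (SE 0.27) and TLR7 by 1.66 (SE 0.29), while TLR3 stood at -0.44 (SE 0.30, adjusted p = 0.289). Of 24 heat shock protein genes and pseudogenes 11 fell and none rose, with a median of -0.42, among them the mitochondrial chaperone genes HSPA9 (-0.86, SE 0.11), HSPE1 (-0.86, SE 0.12) and HSPD1 (-0.75, SE 0.11). All 4 tested platelet glycoprotein genes and all 9 MCM genes fell, most of which the cell cycle and megakaryocyte lists also hold. Of 10 chaperonin genes and pseudogenes 5 fell, of 4 CD1 genes 3 fell, and of 15 HLA class II genes 0 passed in edgeR, against 4 at an unadjusted p under 0.05 and 2 in DESeq2. The families named with a direction kept it under the other scalings tried.

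Genes other than CARM1 fell as consistently as CARM1, and many of them share a 3' UTR word. Carriers of TCCTTCT had z = -14.2, below the lowest z of 100 permutations (-5.37), and its z was -9.29 in genes not used to find it, where 41 of the 100 most significant falling genes carried it against 18.0 expected from 3' UTR length (exact conditional test within classes of length, two-sided, p = 1.78e-09), which is consistent with silencing of other transcripts through the seed of the knockdown hairpin, the short stretch of the guide that pairs with a target. The permutations and the exact test take genes as independent, although genes of the same 6 libraries may vary together. Neither measures the spread between samples. Base composition is argued against, since 5.88% of the 34 other words made of the same bases fell below the permutations, and so is miR-223, whose seed match had z = 1.22. A microRNA of the cell with the same seed was not tested, and the hairpin sequence is not given in the sources used here. The highest z among words of rising genes, 5.18, lay just above the highest of the permutations, 5.04.

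Cell cycle and ribosome biogenesis genes were lower and monocyte and lysosome genes higher, and the tables argue against some technical explanations. Thinning all libraries to the smallest total moved the 4 list medians by at most 0.0128. Random thinning keeps the expected share of each gene, so little movement was foreseeable and this step cannot decide on depth. The group means of the totals were close to begin with (25249400 and 25847500). The trend on GC content and transcript length was weak, from -0.07 to 0.14 over the middle 98% of genes, and its removal left the medians at 0.533 or more in size. Of the falling lists, members without a 3' UTR match had medians of -0.85 and -1.02. Carriers of the word in coding sequence were also lower (z = -7.29), but members with a match in neither place had medians of -0.85 and -0.97, which argues against direct silencing as the whole cause of the falls, while for the rising lists direct silencing has no bearing. A lower share of progenitors would raise markers of other cell types alike, but megakaryocyte markers had a median of -0.70 and stem and progenitor markers one of 0.53. Their standard errors, 0.21 and 0.18, come from the spread over genes taken as independent, not over samples. Both calls were lost with an estimated correlation, and the megakaryocyte call also with fry and without control replicate 2. The medians therefore argue only weakly against this cause, and a rise of monocytic cells alone stays open. Indirect effects of silencing transcripts other than CARM1, if any occurred, cannot be told apart from those of CARM1 loss. Both would be present in every knockdown library, and no second hairpin is named in the labels. A match was carried by 31.3% of falling genes, against 21.1% of genes that did not pass and 15.1% of higher genes. Loss of PRMT4 itself may underlie the pattern and remains a hypothesis, untested here for want of a second hairpin.

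Dividing the 6 samples into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real division gave 4923 genes and was the 1 with as many, and the highest of the others gave 0 in edgeR, with at most 671 genes at an unadjusted p under 0.05. Of the 4 divisions that part all 3 pairs, the real one gave 7156 genes with the replicate block and the others 0. For gene lists, 2 of the 10 divisions, the real one included, gave 16, and the highest of the others also gave 16, with control replicates 1 and 3 beside knockdown replicate 3. The other 9 gave 15, 12, 14, 12, 5, 16, 15, 7 and 14, and 1 that called 14 lists had 6 genes at an unadjusted p under 0.05. Every other division mixes the groups 2 to 1, so it still holds part of the group difference, which widens the spread for gene calls and leaves a difference for lists.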
